A study of Mus musculus with 16 samples.

How the data were processed

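RNA sequencing of mouse hepatocytes was analysed in 16 libraries of 5 groups. Hepatocytes were cultured alone (n = 3), with Phgdh wild-type cancer cells (n = 3), with Phgdh knockout cancer cells (n = 3), with wild-type cells and a CXCR2 inhibitor (n = 3), or with knockout cells and the inhibitor (n = 4). Groups were taken from the sample labels, which name hepatocytes as the source of every library. The series' own design text speaks instead of cancer cells as the sequenced material, in culture alone or with hepatocytes, so the labels and that text conflict, and the labels were followed. The labels state no vehicle, dose, duration, culture format or batch, and no group received the inhibitor without cancer cells. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these libraries.

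Total RNA was extracted with the RNeasy mini kit and libraries followed Novogene's protocols, per the labels' protocols. Reads were aligned with HISAT2, and GRCm38 and mm10 were named as builds, per the submitters' processing notes. The HISAT2 version, the counting tool, the annotation release and the strandedness are not given in the sources used here. The deposited values were given by the authors as FPKM, that is fragments per kilobase of gene length and per M fragments. They covered 54532 genes and 16 libraries with no pooling of replicates. Multiplying each value by the gene length of the same table gave whole multiples of 1 step in each library, with 100% of values within 0.1 of a whole number. Whole fragments could thus be recovered, at 15.0 to 21.3 M per library. One fragment in a gene of 1 kb corresponded to 0.0457 to 0.0648 FPKM, which sets the precision of low values. PCR duplicates cannot be told from separate molecules, so this covers counting error only. The sum of recovered fragments over the divisor used by the authors averaged 1.03 in monoculture, 1.00 in both co-cultures without the inhibitor, and 0.972 and 0.971 in the wild-type and knockout co-cultures with it. The divisor thus differed from the plain sum of fragments, and by group. In the table, 27 gene symbols had been turned into dates and were left as they stood. Of its gene identifiers, 54409 were found in GENCODE M21, 98.3% of them at the same coordinates.

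FPKM values were used as deposited, without further scaling, as log2(FPKM + 1). Genes with a mean of 1 FPKM or more over the 16 libraries were tested, 11395 in all, of which 10226 were protein coding. One linear model with a mean per group was fitted to all libraries with limma 3.58.1 in R 4.3.3, with 11 residual degrees of freedom and moderated variances with an intensity trend. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. There were 8 comparisons, namely each co-culture against monoculture, knockout against wild-type co-culture without and with the inhibitor, the inhibitor effect in each genotype, the difference of both inhibitor effects (an interaction), and the wild-type co-culture with the inhibitor against monoculture. Comparisons that share libraries are not independent. Overlaps between them were set beside the number that independent calls would give and beside 20 simulated data sets with no change in any group and the same shared libraries.

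Gene lists were fixed before the data were examined, as were the comparisons, the test, the rule for named genes and the first set of alternatives. They cover serine synthesis, serine and glycine breakdown with one-carbon metabolism, neutral amino acid transporters, ATF4 targets, the unfolded protein response, hepatocyte secreted proteins and identity factors, cytochrome P450 enzymes, acute phase, NF-kB targets, the CXCR2 axis, interferon-stimulated genes, STAT3 targets, gluconeogenesis, glycolysis and hypoxia, fatty acid oxidation, lipogenesis, cholesterol, urea cycle, proliferation, p53, YAP, TGF-beta, NRF2 and immediate early genes. Marker lists for pancreatic cancer epithelium, cholangiocytes, stellate cells, Kupffer cells, endothelial cells and neutrophils, and the mitochondrially encoded transcripts, complete the 31 lists. Of these, 27 had at least 3 tested members and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera was repeated with an estimated correlation, and where that ended a call its p is given beside it. Counts of members past the threshold are given over all genes tested and adjusted over the list alone.

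Genes were named by a fixed rule. It always took Phgdh, Psat1, Psph, Shmt1, Shmt2, Cxcr1, Cxcr2 and Alb. It then took the protein-coding genes with the largest positive and negative fold changes past the threshold whose libraries did not overlap between both groups, 10 each way in the first 5 comparisons and 5 each way in the last 3 (without the overlap condition for the interaction). Chance gives such a separation for 10% of genes with 3 against 3 libraries. Up to 4 members of each list with the smallest adjusted p were added. Some genes that the rule took are not reported here. Of 274 genes so named, 33 overlapped another tested gene on the genome, and with unknown strandedness their values may include its reads.

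Alternatives changed 1 choice at a time. They were pseudocounts of 0.1 and 0.5 in place of 1, no filter or a mean of 5 FPKM, scaling by the median of ratios, scaling without mitochondrial genes and the top 50 genes, quantile normalization, a fit of only the libraries compared, no intensity trend, array weights, a replicate block, an absolute log2 fold change of at least 1, and leaving out each library in turn. Scaling by the median of ratios gave 7069 changed genes in place of 7070 for wild-type co-culture against monoculture. The deposited values thus already stood near that scale, so this alternative could move little. Added after seeing the data were the removal of each chromosome's median, the removal of medians in 20 bins of GC content and of gene length, and a fit without the 7 libraries with the inhibitor. GC values were at hand for 11385 tested genes (99.9%). Principal components were computed on the centred log2 values of the tested genes. On data simulated from the libraries with 200 altered genes, the test recovered 80% of changes of 0.5 on the log2 scale and 97% of changes of 1, with 17 unaltered genes called. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Deposited data other than the FPKM table were not used here.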

Results

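Gene expression was measured by RNA sequencing in mouse hepatocytes, labelled as a cell line, that had been cultured alone or with cancer cells carrying (wild type) or lacking (knockout) Phgdh. Phgdh encodes the first enzyme of serine synthesis from glucose. The series concerns serine supplied by hepatocytes in liver metastasis of pancreatic cancer. Some co-cultures also received an inhibitor of CXCR2, a receptor for neutrophil-attracting chemokines. Recovered fragments per library were 16.4 to 21.02 M in monoculture, 16.2 to 20.9 M in wild-type and 18.1 to 21.2 M in knockout co-culture. With the inhibitor they were 15.002 to 17.1 M for wild-type and 16.1 to 21.3 M for knockout cells. Throughout, ± marks the SD of an FPKM mean or the SE of a log2 fold change, with n = 4 in the knockout co-culture with the inhibitor and n = 3 in the other groups.

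In the principal component analysis, the first component held 59.1% of the variance and the second 27.3%. The 7 libraries with the inhibitor lay between -38.1 and -34.8 on the first component, the 6 co-culture libraries without it between 36.4 and 38.2, and monoculture between 11.4 and 11.6. Monoculture stood apart on the second component (46.6 to 48.0). The third component (2.99% of the variance) set wild-type co-culture replicate 1 apart, at 20.1. It also split the inhibitor groups (wild type -6.33 to 7.71, knockout -6.02 to 7.45) and knockout co-culture (-10.2 to 5.71). Replicate numbers did not pair libraries across groups, since the correlations of deviations between same-numbered libraries ran from -0.300 to 0.270 with a median of 0.0104.

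**Figure D1:**
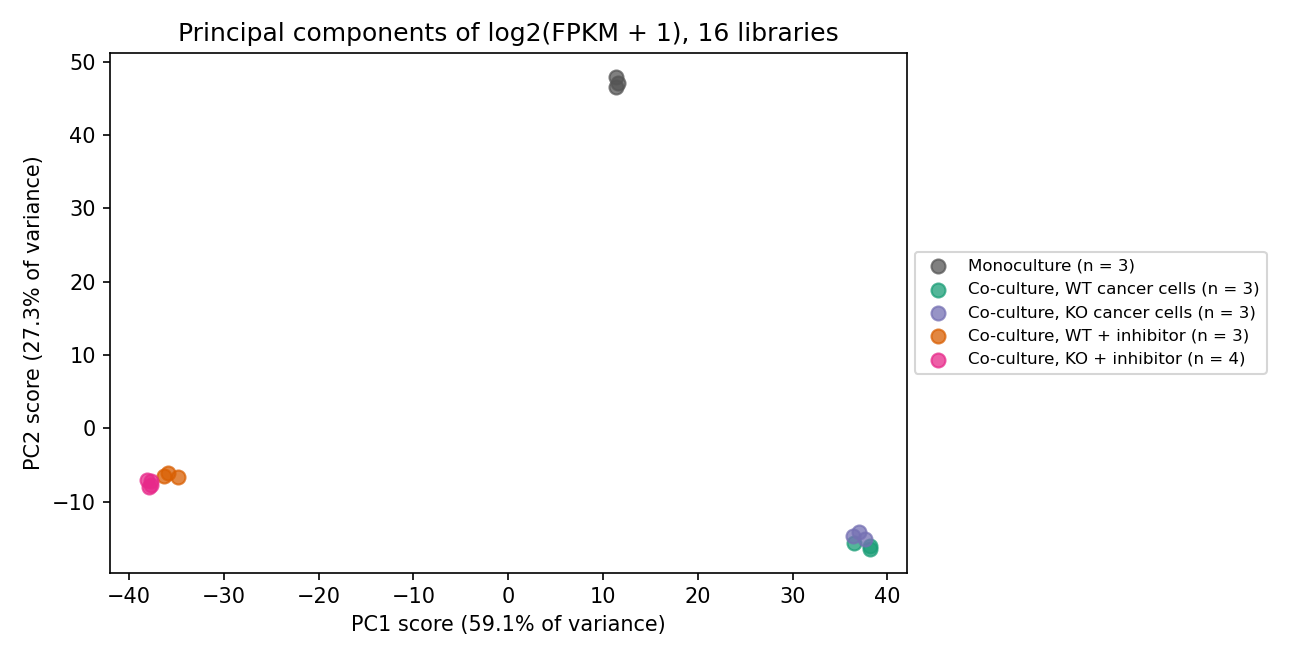
Principal components of log2(FPKM + 1) of the 11395 tested genes, with 1 point per library, the share of variance on each axis and colours for the 5 groups. The libraries with the inhibitor lie at -34.8 or below on the first component and all other libraries at 11.4 or above.

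By the labels the knockout was in the cancer cells, so Phgdh of the hepatocytes is not by itself a check of the labels. Phgdh (ENSMUSG00000053398, chromosome 3, 98313170 to 98339990, GRCm38) was read at 203 to 207 FPKM in the 3 monoculture libraries, 195 to 206 in wild-type and 193 to 201.1 in knockout co-culture. With the inhibitor it was 155 to 160.2 in wild-type and 146 to 157 in knockout co-culture. Psat1 (ENSMUSG00000024640, chromosome 19, 15904678 to 15947337) and Psph (ENSMUSG00000029446, chromosome 5, 129765558 to 129787449) encode the next enzymes of the pathway, and Shmt1 (chromosome 11, 60788104 to 60811718) and Shmt2 (chromosome 10, 127517123 to 127522444) interconvert serine and glycine in cytosol and mitochondria. Cxcr1 was listed at 0 in every library, and Cxcr2 at 0 in all but knockout co-culture replicate 3 (0.0727 FPKM) and wild-type inhibitor replicate 1 (0.0373 FPKM), so the inhibitor's named target was near or under the detection limit in these libraries.

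**Figure D2:**
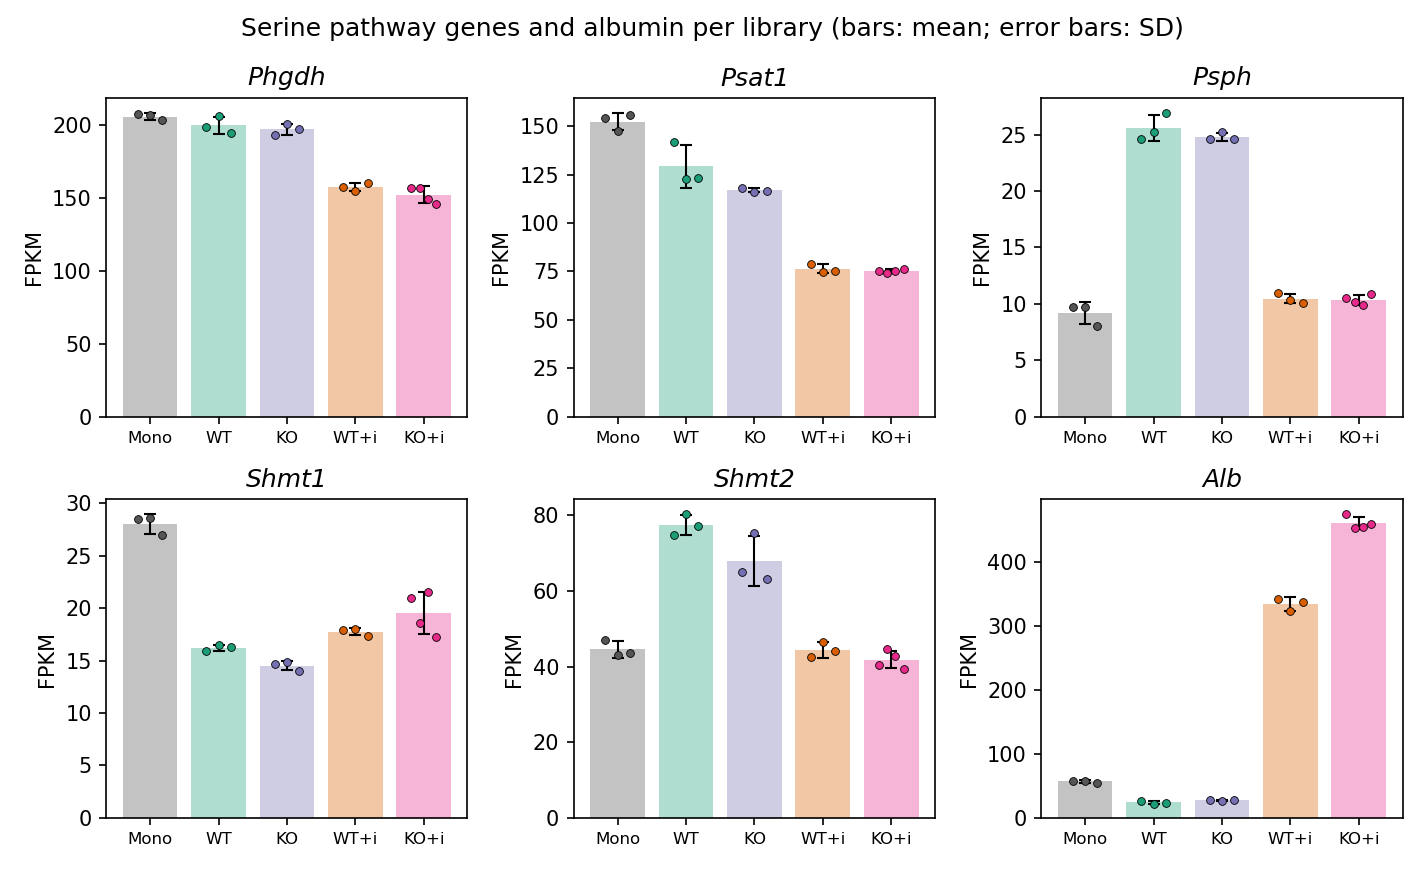
FPKM of Phgdh, Psat1, Psph, Shmt1, Shmt2 and Alb in the 5 groups, with 1 point per library, bars for the mean and error bars for the SD. Psph averaged 9.17 FPKM in monoculture, 25.6 in wild-type co-culture and 10.5 with the inhibitor.

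Wild-type co-culture against monoculture asks what the cancer cells change. Chemokine, cell cycle and acute phase transcripts were lower in co-culture, and transcripts of the unfolded protein and integrated stress responses were higher. Ccl2, which encodes a monocyte-attracting chemokine (chromosome 11, 82035571 to 82037453), was 878 ± 12.7 FPKM in monoculture and 9.56 ± 0.717 in co-culture (log2 fold change -6.38 ± 0.05). Rrm2, a subunit of ribonucleotide reductase, went from 42.2 ± 2.24 to 1.55 ± 0.0902 FPKM (-4.08 ± 0.07). In the other direction, Trib3, a pseudokinase induced by ATF4 (chromosome 2, 152337422 to 152344032), went from 13.2 ± 1.01 to 154 ± 16.4 FPKM (3.44 ± 0.08), and the endoplasmic reticulum chaperone Hspa5 from 236 to 1171 FPKM (2.31 ± 0.04).

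The largest rises after the overlap condition were Angptl6 (log2 fold change 3.72), Cdsn (3.47), Trib3, the epidermal growth factor family ligands Areg (3.30) and Btc (3.19), the bile acid side chain enzyme Acox2 (3.19), Akr1b7 (3.12), Reep6 (3.01), Stbd1 (3.001) and Soat2 (2.88), a cholesterol esterifying enzyme. Angptl6 overlaps A230050P20Rik, whose own log2 fold change was 0.29. Besides Ccl2 and Rrm2, the largest falls were the chemokines Ccl7 (-4.97), Cxcl1 (-4.67) and Cxcl5 (-3.91), the matricellular protein gene Cyr61 (-4.59), haptoglobin Hp (-4.02), the small heat shock protein gene Cryab (-3.85), Serpinb9b (-3.85, with near-identical relatives, so uncertain) and the mitotic cyclin Ccnb2 (-3.84).

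Of the 3 serine synthesis genes, Psph rose (9.17 to 25.6 FPKM, log2 fold change 1.39 ± 0.06, adjusted p = 7.21e-11), Psat1 fell (-0.24 ± 0.05, adjusted p = 6.38e-04) and Phgdh did not pass (-0.04 ± 0.04, adjusted p = 0.319). As a list they did not pass (camera adjusted p = 0.726), with a median of -0.04 and a mean of 0.37, opposite in sign, and 2 members passed adjusted over the list alone. The Psat1 call was lost under quantile normalization (log2 fold change -0.13, adjusted p = 0.0718). Psph overlaps Cct6a, whose own log2 fold change was -0.19. Shmt1 fell (-0.75 ± 0.06) and Shmt2 rose (0.78 ± 0.07). Of 24 genes of serine and glycine breakdown and one-carbon metabolism, 12 rose, 9 fell and 3 did not pass, with 21 adjusted over the list alone (median log2 fold change 0.16, camera adjusted p = 0.325). They include the cystathionine lyase Cth (2.57), the mitochondrial folate enzymes Aldh1l2 (2.85) and Mthfd2 (0.87), and the glycine cleavage enzyme Gldc (-1.53). Among 17 neutral amino acid transporters, 9 rose, 3 fell and 5 did not pass, with 12 adjusted over the list alone (median log2 fold change 0.47, camera adjusted p = 0.0149). The serine and alanine carrier Slc1a4 (2.62), the heavy chain Slc3a2 (2.10) and the cystine carrier Slc7a11 (1.80) rose, and the taurine carrier Slc6a6 fell (-1.51).

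Stress response lists rose as groups. Of 23 ATF4 and integrated stress response targets, 20 rose, 1 fell and 2 did not pass, with 21 adjusted over the list alone (median log2 fold change 1.19, camera adjusted p = 7.00e-12). Among these were the proline synthesis genes Pycr1 (2.36) and Aldh18a1 (1.76) and the tryptophan tRNA synthetase Wars (1.85). All 19 tested genes of the unfolded protein response rose, 19 adjusted over the list alone (median log2 fold change 1.56, camera adjusted p = 4.97e-16). They included the chaperone Hyou1 (2.48), the disulfide isomerase Pdia4 (1.93) and the degradation factor Sel1l (1.56).

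Inflammatory lists fell as groups. Of 25 NF-kB targets and chemokines, 1 rose, 23 fell and 1 did not pass, with 24 adjusted over the list alone (median log2 fold change -1.28, camera adjusted p = 2.88e-13). These included the NF-kB inhibitor Tnfaip3 (-3.63) and the macrophage growth factor Csf1 (-1.89). Of the 4 tested genes of the CXCR2 axis, the ligands Cxcl1, Cxcl5 and Cxcl2 (-2.86) fell and Mif did not pass, with 3 adjusted over the list alone (median log2 fold change -3.39, camera adjusted p = 0.00227). Of 21 acute phase genes, 2 rose, 15 fell and 4 did not pass, with 17 adjusted over the list alone (median log2 fold change -1.01, camera adjusted p = 4.31e-05). Falls included those of complement C3 (319 to 44.8 FPKM, -2.81), ceruloplasmin Cp (-2.54) and the lipopolysaccharide-binding protein Lbp (-1.61). All 13 tested STAT3 and gp130 targets fell, 13 adjusted over the list alone (median log2 fold change -0.60, camera adjusted p = 6.17e-05). Examples were the feedback inhibitor Socs3 (-1.67) and the kinase Pim1 (-1.57). Among 34 interferon-stimulated genes, 9 rose, 16 fell and 9 did not pass, with 25 adjusted over the list alone, and the list did not pass (median log2 fold change -0.16, camera adjusted p = 0.304).

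All 26 tested proliferation genes fell, 26 adjusted over the list alone (median log2 fold change -2.61, camera adjusted p = 2.42e-19). The cycling marker Mki67 went from 21.6 to 0.719 FPKM (-3.71), topoisomerase Top2a fell by 3.17 and the replication factor Mcm3 by 2.63 on the log2 scale. Of 23 YAP and dedifferentiation genes, 2 rose, 20 fell and 1 did not pass, with 22 adjusted over the list alone (median log2 fold change -1.04, camera adjusted p = 4.66e-09). Among them were Ankrd1 (-2.71) and the actin gene Actb (-1.55). The gene Areg of that list rose. Of 13 TGF-beta targets and matrix genes, 1 rose, 11 fell and 1 did not pass, with 12 adjusted over the list alone (median log2 fold change -0.99, camera adjusted p = 7.10e-06). Falls included those of the crosslinking enzyme Loxl2 (-2.09) and thrombospondin Thbs1 (-2.38). Of 22 immediate early genes, 0 rose, 19 fell and 3 did not pass, with 19 adjusted over the list alone (median log2 fold change -1.004, camera adjusted p = 9.51e-09). Examples were the phosphatase Dusp1 (-3.25) and the transcription factors Egr1 (-1.29) and Fosl2 (-1.78).

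Of 19 hepatocyte secreted proteins and identity factors, 3 rose, 13 fell and 3 did not pass, with 16 adjusted over the list alone (median log2 fold change -0.50, camera adjusted p = 0.0149). Albumin (Alb, chromosome 5, 90460897 to 90476602) went from 57.1 ± 1.81 to 24.3 ± 2.56 FPKM (-1.21 ± 0.06), transthyretin Ttr fell (-1.83) and the retinol-binding protein Rbp4 rose (1.66). Of 20 cholesterol synthesis and uptake genes, 0 rose, 19 fell and 1 did not pass, with 19 adjusted over the list alone (median log2 fold change -0.75, camera adjusted p = 4.56e-09). Among these was the sterol carrier Stard4 (-1.75). Of 13 lipogenesis genes, 1 rose, 11 fell and 1 did not pass, with 13 adjusted over the list alone (median log2 fold change -0.57, camera adjusted p = 7.72e-05). They included the desaturases Fads2 (-2.83) and Scd1 (-1.02). Of 12 cytochrome P450 and drug metabolism genes, 3 rose, 3 fell and 6 did not pass, with 6 adjusted over the list alone, and the list did not pass (median log2 fold change -0.06, camera adjusted p = 0.970). The sulfotransferase Sult1a1 fell (-2.86) and Cyp1a1 rose (1.76). Among 26 glycolysis and hypoxia genes, 9 rose, 13 fell and 4 did not pass, with 24 adjusted over the list alone, and the list did not pass (median log2 fold change -0.34, camera adjusted p = 0.284). The angiogenic factor Vegfa rose (2.73) and lactate dehydrogenase Ldha fell (-0.88). Mitochondrially encoded transcripts held 3.41 to 3.79% of fragments in monoculture and 3.49 to 4.57% in co-culture.

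In all, 7070 of the 11395 genes changed, 3432 higher and 3638 lower, of which 296 rose and 724 fell at least 2-fold. The majority direction depended on the scaling, with 48.5% higher in these calls, 56.0% when scaled without mitochondrial genes and the top 50 genes, and 55.9% after quantile normalization. Lists past the threshold numbered 17 with the preset and 15 with an estimated correlation. The single mitochondrial gene past the threshold, mt-Co3 (log2 fold change 0.51), lost its call without monoculture replicates 1 or 3 (adjusted p = 0.0783 and 0.0999) or wild-type co-culture replicate 1 (adjusted p = 0.169).

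**Figure D3:**
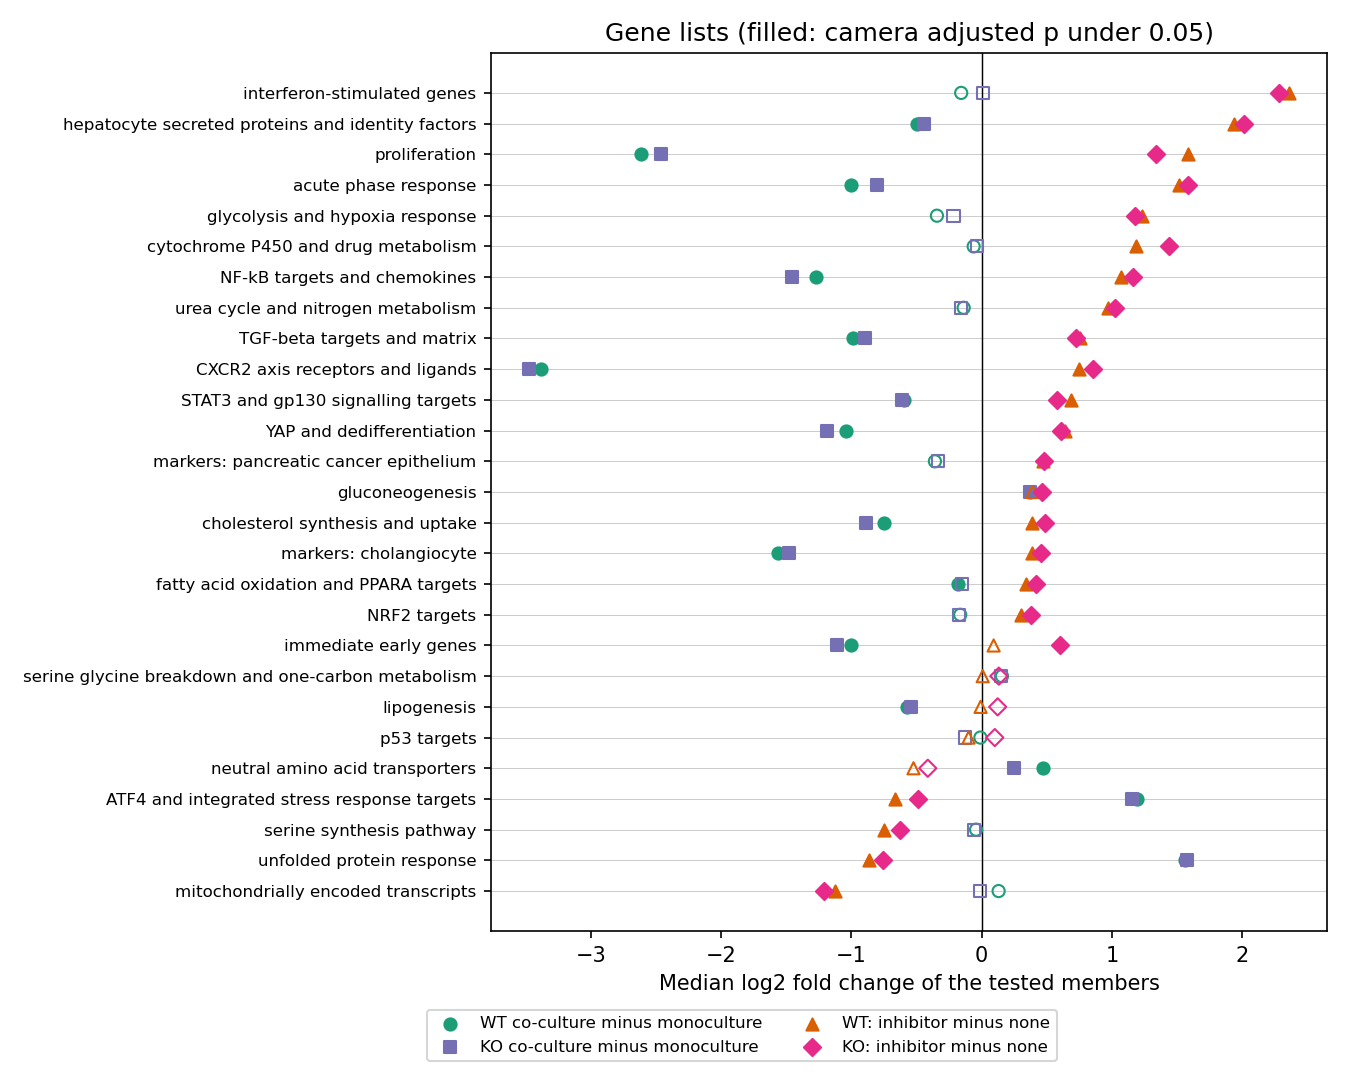
Median log2 fold change of the tested members of each of the 27 gene lists for both co-cultures against monoculture and for the inhibitor in both genotypes, with filled symbols where the camera adjusted p was under 0.05. The proliferation list lay at -2.61 in wild-type co-culture and at 1.58 for the inhibitor added to it.

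Knockout co-culture against the same monoculture asks what cancer cells without Phgdh change. Leading genes included Ccl2 (16.1 ± 0.625 FPKM in co-culture, log2 fold change -5.68 ± 0.05), Ccl7 (-4.76), Cyr61 (-4.72) and Cxcl1 (-4.60) among the falls, and Angptl6 (3.67), Acox2 (3.57), Trib3 (3.55) and Aldh1l2 (2.85) among the rises. Psph rose (1.35 ± 0.06), Shmt2 rose (0.59 ± 0.07), Psat1 fell (-0.38 ± 0.05), Shmt1 fell (-0.90 ± 0.06) and Phgdh did not pass (-0.06 ± 0.04, adjusted p = 0.154). Albumin was 27.8 ± 0.671 FPKM in co-culture (-1.01 ± 0.06). The serine synthesis list again had a median (-0.06) and a mean (0.30) of opposite sign and did not pass (camera adjusted p = 0.907), with 2 adjusted over the list alone. All 26 proliferation genes fell (26 adjusted over the list alone, median log2 fold change -2.46, camera adjusted p = 1.34e-19) and all 19 unfolded protein response genes rose (19 adjusted over the list alone, median log2 fold change 1.57, camera adjusted p = 7.86e-16). Of 23 ATF4 targets, 20 rose, 1 fell and 2 did not pass (21 adjusted over the list alone, camera adjusted p = 3.18e-11). Of 25 NF-kB targets, 1 rose, 23 fell and 1 did not pass (24 adjusted over the list alone, camera adjusted p = 1.07e-13). Among the 22 immediate early genes, 0 rose, 21 fell and 1 did not pass (21 adjusted over the list alone, camera adjusted p = 1.21e-10).

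The falls of mt-Nd1 (-0.19) and mt-Nd2 (-0.30) lost their calls without knockout replicate 2 (adjusted p = 0.130 and 0.180), monoculture replicate 2 (0.0967 and 0.114) or monoculture replicate 3 (0.0771 and 0.0704). Against monoculture 7011 genes changed with knockout cells, 3457 higher and 3554 lower (49.3% higher, or 55.3% and 56.2% under the same pair of scalings). Of these, 6273 changed in the same direction with wild-type cells and 6 in the opposite one, where independent calls would give 2176 shared genes. Fold changes of both comparisons correlated across genes at r = 0.973, with a covariance of 0.395. Simulated groups without any change but with the same shared monoculture libraries gave an r of 0.503, a covariance of 0.00791 and 0 shared genes. Shared controls thus give little of the excess. At an absolute log2 fold change of at least 1, 878 genes were shared. Genes are not independent replicates in these correlations.

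Knockout against wild-type co-culture asks whether Phgdh in the cancer cells matters to hepatocytes. Immediate early genes were lower beside knockout cells, and several plasma protein genes and Ccl2 were higher. Egr1, an immediate early transcription factor (chromosome 18, 34859823 to 34864984), was 72.0 ± 0.760 FPKM beside wild-type and 38.3 ± 1.44 beside knockout cells (log2 fold change -0.89 ± 0.03, adjusted p = 3.31e-09). Fosb of the same class went from 4.11 ± 0.720 to 1.23 ± 0.122 FPKM (-1.19 ± 0.09), and Ptprn, a protein of secretory granules, from 49.5 ± 2.83 to 25.7 ± 0.746 (-0.92 ± 0.05). Transthyretin Ttr (chromosome 18, 20665250 to 20674324) was 23.9 ± 1.11 FPKM beside wild-type and 50.4 ± 2.99 beside knockout cells (1.04 ± 0.06), and angiotensinogen Agt 5.99 ± 0.400 and 11.9 ± 0.385 (0.88 ± 0.08).

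Other calls of this comparison that passed in each alternative apart from the threshold on fold size were the glucose transporter Slc2a2 (log2 fold change 0.79 ± 0.06), Smoc1 (0.73 ± 0.07), Ccl2 (0.70 ± 0.05), complement C3 (0.53 ± 0.03) and the growth factor binding protein Igfbp3 (-0.59 ± 0.07). In a fit of only the 6 libraries compared, the calls of Lmcd1 (0.60), Hsd17b13 (0.67), Fam84a (-0.57) and Dqx1 (-0.55) ended (adjusted p = 0.0678, 0.160, 0.0933 and 0.0933). Single libraries decided 7 more. Cxcl17 (0.77) lost its call without wild-type replicates 1 or 3 or knockout replicates 1 or 3 (adjusted p up to 0.113). The same held for Wfdc3 (0.66) without wild-type replicate 1 or any knockout replicate (up to 0.127), for Sprr1a (-0.68) without wild-type replicates 2 or 3 or knockout replicates 1 or 2 (up to 0.0795), and for R3hdml (-0.65) without wild-type replicates 2 or 3 or knockout replicate 3 (up to 0.0879). Apoe (0.60) and Il11 (-0.57) lost theirs without any of 13 libraries and Tigit (-0.57) without any of 8, with adjusted p up to 0.160, 0.162 and 0.154.

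Of 22 immediate early genes, 0 were higher, 10 were lower and 12 did not pass, with 11 adjusted over the list alone (median log2 fold change -0.17, camera adjusted p = 4.22e-12, adjusted p = 0.0125 with an estimated correlation). Members were Ier2 (-0.49) and the antiproliferative gene Btg2 (-0.40). Of 21 acute phase genes, 6 were higher, 0 were lower and 15 did not pass, with 8 adjusted over the list alone (median log2 fold change 0.18, camera adjusted p = 1.88e-07). Among these were Lbp (0.35) and Cp (0.37). Of 19 hepatocyte secreted proteins and identity factors, 3 were higher, 2 were lower and 14 did not pass, with 10 adjusted over the list alone (median log2 fold change 0.12, camera adjusted p = 0.00897). In that list apolipoprotein Apoh rose (0.56), the transcription factor Hnf4a fell (-0.27) and albumin did not pass (0.19, adjusted p = 0.0960). Of 26 proliferation genes, 5 were higher, 1 was lower and 20 did not pass, with 10 adjusted over the list alone (median log2 fold change 0.09, camera adjusted p = 1.69e-04), Top2a (0.27) and Rrm2 (0.38) being higher and the cyclin Ccnd1 (-0.21) lower. Of 23 YAP and dedifferentiation genes, 0 were higher, 4 were lower and 19 did not pass, with 7 adjusted over the list alone (median log2 fold change -0.06, camera adjusted p = 0.00125). The calls of Ier2, Btg2, Lbp, Cp, Apoh, Hnf4a, Top2a, Rrm2 and Ccnd1 ended in the fit of only the libraries compared (adjusted p = 0.114, 0.114, 0.0933, 0.205, 0.0933, 0.240, 0.270, 0.202 and 0.239).

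The p53 list was lower (median log2 fold change -0.09, 3 adjusted over the list alone, camera adjusted p = 0.00428) and the cholangiocyte list higher (0.13, 3 adjusted over the list alone, 0.00917). In 6 further lists the camera call was lost with an estimated correlation, namely the unfolded protein response (median -0.08, camera adjusted p = 3.56e-04, adjusted p = 0.0619 with an estimated correlation), interferon-stimulated genes (median 0.06, 0.00877, adjusted p = 0.0619 with an estimated correlation), fatty acid oxidation (median 0.07, 0.0107, adjusted p = 0.111 with an estimated correlation), cholesterol (median -0.05, 0.0107, adjusted p = 0.145 with an estimated correlation), cytochrome P450 (median 0.05, 0.0487, adjusted p = 0.111 with an estimated correlation) and glycolysis (median -0.06, 0.0487, adjusted p = 0.298 with an estimated correlation). None of the serine genes passed, with Phgdh at -0.02 ± 0.04 (adjusted p = 0.882), Psat1 at -0.14 ± 0.05 (0.167), Psph at -0.04 ± 0.06 (0.845), Shmt1 at -0.15 ± 0.06 (0.297) and Shmt2 at -0.19 ± 0.07 (0.164). The serine synthesis list did not pass either (camera adjusted p = 0.172, 1 adjusted over the list alone).

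Between both genotypes 341 genes changed, 188 higher and 153 lower, with 1 gene each way reaching 2-fold. Scaling without mitochondrial genes and the top 50 genes moved the higher share from 55.1% to 43.8%, with 265 genes changed. The count dropped to 17 in the fit of only these 6 libraries and to 82 without the 7 inhibitor libraries, and it was 1384 with array weights. Leaving out 1 library gave 199 without wild-type replicate 3, and 175, 197 and 157 without knockout replicates 1, 2 and 3. Of 66 named calls 10 passed in each alternative apart from the threshold on fold size, and 32 were lost on leaving out at least 1 library.

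Adding the CXCR2 inhibitor to wild-type co-culture asks how hepatocytes beside cancer cells differ with it. Liver secretory and interferon-stimulated genes were higher with the inhibitor, chemokine and cell cycle genes that were lower in co-culture were higher again, and stress response and serine synthesis genes were lower. Albumin went from 24.3 ± 2.56 to 335 ± 10.3 FPKM (log2 fold change 3.74 ± 0.06) and Ccl2 from 9.56 ± 0.717 to 291 ± 2.78 (4.79 ± 0.05). Ifit1, an antiviral gene induced by interferon, went from 1.08 ± 0.376 to 60.8 ± 3.35 FPKM (4.90 ± 0.10), and Fos, an immediate early transcription factor, from 30.1 ± 1.75 to 1.76 ± 0.101 (-3.49 ± 0.09).

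These libraries also differed by chromosome. Genes on chromosome 11 had a median log2 fold change of -0.334 relative to all genes, those on chromosome 19 of -0.271 and on chromosome 12 of -0.206, while chromosome 17 stood at 0.241, chromosome 4 at 0.197 and chromosome 16 at 0.190. The highest such value in 1000 shuffles of genes was 0.129. All 7 windows of 20 Mb on chromosome 11 lay below 0, from -0.402 to -0.259. Per library, the chromosome 11 deviation was -0.317 to -0.282 in the 7 libraries with the inhibitor and -0.0159 to 0.0184 in the other 9. Mitochondrially encoded transcripts held 1.86 to 2.11% of fragments with the inhibitor and 3.49 to 4.57% without it. Of the 13 mitochondrial genes, 0 rose, 12 fell and 1 did not pass, with 12 adjusted over the list alone (median log2 fold change -1.12, camera adjusted p = 4.84e-05, adjusted p = 0.134 with an estimated correlation).

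**Figure D4:**
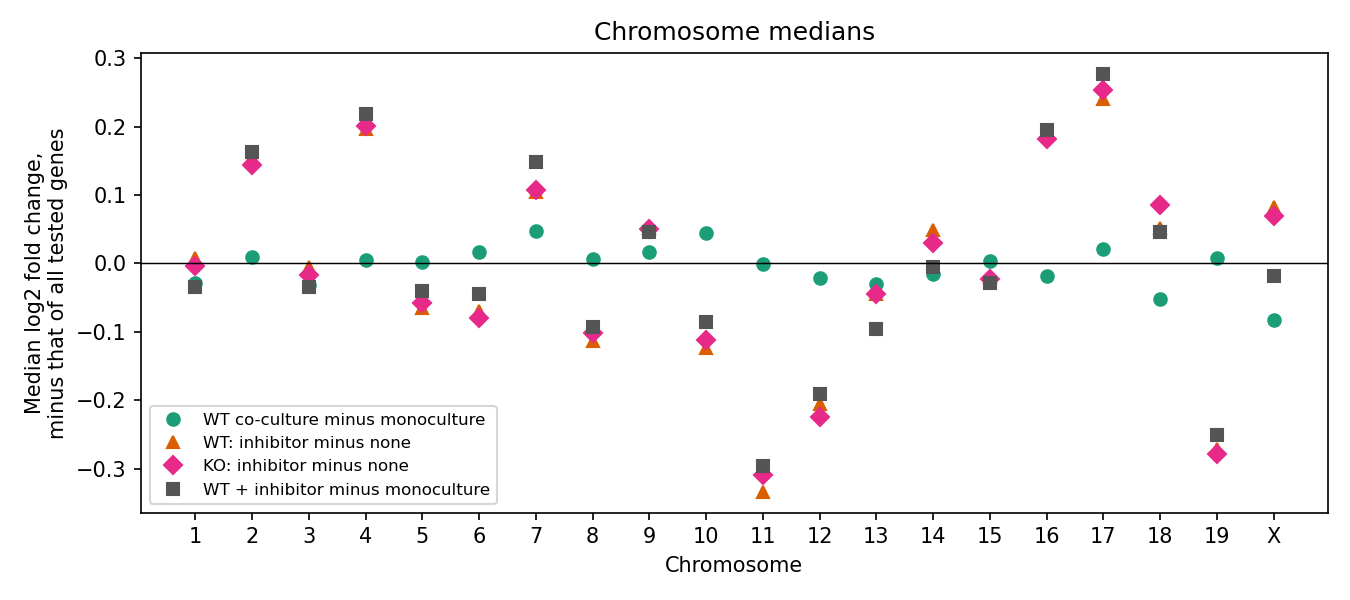
Median log2 deviation of the tested genes on each chromosome relative to all genes, with 1 point per chromosome and comparison, for wild-type co-culture against monoculture, the inhibitor in both genotypes, and wild-type co-culture with the inhibitor against monoculture. Chromosome 11 lies at -0.334 for the inhibitor in wild-type co-culture, while the value furthest from 0 for wild-type co-culture against monoculture is -0.0827 on chromosome X.

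All 3 serine synthesis genes fell (3 adjusted over the list alone, median log2 fold change -0.75, camera adjusted p = 0.00912). Phgdh went from 199.9 ± 5.79 to 158 ± 2.69 FPKM (-0.34 ± 0.04), Psat1 from 129 ± 11.04 to 76.4 ± 2.28 (-0.75 ± 0.05) and Psph from 25.6 ± 1.18 to 10.5 ± 0.426 (-1.21 ± 0.06). Psat1 lies on chromosome 19, and with chromosome medians removed its fold change was -0.48. Shmt2 fell (-0.79 ± 0.07). Shmt1, on chromosome 11, did not pass (0.12 ± 0.06, adjusted p = 0.106) but stood at 0.44 with chromosome medians removed (adjusted p = 2.30e-05). Of 24 genes of serine and glycine breakdown and one-carbon metabolism, 11 rose, 9 fell and 4 did not pass, with 20 adjusted over the list alone, and the list did not pass (median log2 fold change 0.01, camera adjusted p = 0.575). Gldc (1.88), the homocysteine-forming enzyme Ahcy (1.31) and Cbs (1.61) rose and Mthfd2 fell (-1.196). Of 17 transporters, 7 rose, 10 fell and 0 did not pass, with 17 adjusted over the list alone, and the list did not pass (median log2 fold change -0.52, camera adjusted p = 0.200), with Slc7a2 (3.28) higher and Slc3a2 (-1.498) and Slc1a4 (-1.46) lower. All 19 unfolded protein response genes fell (19 adjusted over the list alone, median log2 fold change -0.86, camera adjusted p = 1.11e-10). Here Hspa5 stood at -1.03 and Xbp1 at -0.83. Of 23 ATF4 targets, 1 rose, 17 fell and 5 did not pass, with 18 adjusted over the list alone (median log2 fold change -0.66, camera adjusted p = 2.21e-06). Here Wars stood at -1.33 and the transcription factor Atf3 at -1.66.

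All 34 interferon-stimulated genes rose (34 adjusted over the list alone, median log2 fold change 2.36, camera adjusted p = 1.59e-20). Such genes were the transcription factors Stat2 (3.07) and Irf7 (3.85) and the oligoadenylate synthetase Oas1a (3.98). Interferon-related genes among the largest rises were Ifitm3 (5.74), Trim30a (4.92) and Apol9b (4.47), the last pair with near-identical relatives and so uncertain. Of 25 NF-kB targets and chemokines, 23 rose, 1 fell and 1 did not pass, with 24 adjusted over the list alone (median log2 fold change 1.07, camera adjusted p = 4.82e-09). These included Nfkbia (2.18) and Ccl7 (3.17). Ccl2 and Ccl7 lie on chromosome 11, whose median was lower. All 4 tested genes of the CXCR2 axis rose (4 adjusted over the list alone, median log2 fold change 0.74, camera adjusted p = 0.0177), Cxcl1 reaching 8.49 ± 0.411 FPKM (1.61) against 78.2 ± 2.33 in monoculture. Of 21 acute phase genes, 19 rose, 1 fell and 1 did not pass, with 20 adjusted over the list alone (median log2 fold change 1.52, camera adjusted p = 6.92e-09). Here C3 stood at 2.54 and fibrinogen Fga at 3.55. Of 13 STAT3 targets, 9 rose, 1 fell and 3 did not pass, with 10 adjusted over the list alone (median log2 fold change 0.68, camera adjusted p = 0.00349). Here Pim1 stood at 3.22 and Lrg1 at 2.99.

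Of 19 hepatocyte secreted proteins and identity factors, 15 rose, 1 fell and 3 did not pass, with 16 adjusted over the list alone (median log2 fold change 1.94, camera adjusted p = 1.23e-07). Members included apolipoprotein Apoa1 (5.43), fetuin Ahsg (4.42) and Ttr (2.97). Of 12 cytochrome P450 and drug metabolism genes, 11 rose, 1 fell and 0 did not pass, with 12 adjusted over the list alone (median log2 fold change 1.19, camera adjusted p = 2.38e-05). The sulfotransferase Sult1a1 (chromosome 7, 126672865 to 126676432) had the largest rise of all named genes, from 0.257 ± 0.154 to 118 ± 3.43 FPKM (6.57 ± 0.10), while the overlapping Sgf29 stood at -0.04. Of 26 glycolysis and hypoxia genes, 21 rose, 1 fell and 4 did not pass, with 22 adjusted over the list alone (median log2 fold change 1.23, camera adjusted p = 4.82e-09). Here the oxygen sensor Egln3 stood at 3.55 and Ldha at 1.79. Of 26 proliferation genes, 25 rose, 1 fell and 0 did not pass, with 26 adjusted over the list alone (median log2 fold change 1.58, camera adjusted p = 2.69e-12), Mki67 reaching 14.9 ± 0.411 FPKM (3.21). Of 23 YAP genes, 17 rose, 3 fell and 3 did not pass (20 adjusted over the list alone, camera adjusted p = 2.87e-05), and of 13 TGF-beta and matrix genes, 9 rose, 3 fell and 1 did not pass (12 adjusted over the list alone, camera adjusted p = 0.00417). Here Ankrd1 stood at 2.73 and fibronectin Fn1 at 1.92. The cholesterol list also rose (14 rose, 0 fell and 6 did not pass, 14 adjusted over the list alone, median log2 fold change 0.38, camera adjusted p = 3.91e-05). The lipogenesis list did not pass (6 rose, 3 fell and 4 did not pass, 10 adjusted over the list alone, camera adjusted p = 0.115), with a median of -0.01 and a mean of 0.52, opposite in sign, and its median was 0.21 with chromosome medians removed (adjusted p = 0.00600).

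Among the 22 immediate early genes, 11 rose, 7 fell and 4 did not pass, with 18 adjusted over the list alone, and the list did not pass (median log2 fold change 0.09, camera adjusted p = 0.286). The heat shock gene Hspa1b rose (4.97, uncertain because of its near-identical copy Hspa1a, and on chromosome 17, whose median was higher), as did Dusp1 (2.75, also on chromosome 17), while Fos fell on chromosome 12. Besides Fos, the largest falls were the protease Htra1 (-3.30, overlapping Fgfr2 at 1.72), the actin regulators Evl (-3.21, chromosome 12) and Dbn1 (-2.85), Bex1 (-3.15), Nkain1 (-3.001), the neurotrophic factor receptor Gfra1 (-2.97, chromosome 19), Podxl (-2.91), Fam19a5 (-2.84) and Cdsn (-2.702, chromosome 17). Of 14 tested genes of the pancreatic cancer epithelium list, 10 rose, 3 fell and 1 did not pass, with 13 adjusted over the list alone (median log2 fold change 0.47, camera adjusted p = 0.0166), the keratins Krt19 (96.9 FPKM in monoculture, 22.0 in co-culture, 193 with the inhibitor), Krt7 (4.26, 0.580 and 7.86) and Krt20 (33.9, 16.3 and 82.7) being expressed in monoculture as well. The macrophage marker Cd68 stood at 1.34 ± 0.1501 FPKM without and 4.96 ± 0.710 with the inhibitor (1.34).

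Between wild-type co-culture with and without the inhibitor 7584 genes changed, 3821 higher and 3763 lower with it, of which 865 rose and 329 fell at least 2-fold. The higher share of 50.4% became 53.6% when scaled without mitochondrial genes and the top 50 genes, 43.8% after quantile normalization and 47.0% among genes with a mean of at least 5 FPKM. All libraries with the inhibitor and no others had the chromosome pattern, so these changes cannot be assigned to the inhibitor alone. Against the direction of wild-type co-culture versus monoculture went 4044 genes and along it 1159, where independent calls would give 2353 reversed genes. The correlation across genes was -0.497 and simulated groups without change gave -0.494, because both share the wild-type co-culture libraries, while the covariance was -0.223 against -0.00767 simulated. The shared libraries thus give little of the excess. With chromosome medians removed 7287 genes changed. Of the genes that differed with the genotype of the cancer cells, 180 changed in the same direction with the inhibitor and 124 in the opposite one, against 114 for independent calls, with an r of 0.135 beside 0.494 simulated and a covariance of 0.0140 beside 0.00764.

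In knockout co-culture the inhibitor asks the same question beside cancer cells without Phgdh. Albumin went from 27.8 ± 0.671 to 461 ± 9.61 FPKM (log2 fold change 4.01 ± 0.05), Apoa1 from 0.597 ± 0.225 to 93.4 ± 7.84 (5.89 ± 0.16), Sult1a1 rose by 6.58 ± 0.10 and the retinaldehyde dehydrogenase Aldh1a1 by 4.30 ± 0.06. The cell cycle inhibitor gene Cdkn2a fell from 29.4 ± 3.83 to 2.50 ± 0.508 FPKM (-3.12 ± 0.13) and the calcium channel gene Cacna1h was at -2.72. Phgdh (-0.37 ± 0.03), Psat1 (-0.63 ± 0.05, -0.35 with chromosome medians removed), Psph (-1.19 ± 0.06) and Shmt2 (-0.68 ± 0.06) fell and Shmt1 rose (0.40 ± 0.06, 0.71 with chromosome medians removed). All 34 interferon-stimulated genes rose (34 adjusted over the list alone, median log2 fold change 2.28, camera adjusted p = 5.09e-19), and all 19 unfolded protein response genes (19 adjusted over the list alone, median log2 fold change -0.76, camera adjusted p = 4.09e-09) and 3 serine synthesis genes (3 adjusted over the list alone, median log2 fold change -0.63, camera adjusted p = 0.0103) fell. Of 19 hepatocyte proteins and factors, 17 rose, 1 fell and 1 did not pass (18 adjusted over the list alone, camera adjusted p = 1.37e-08), and of 26 proliferation genes, 25 rose, 1 fell and 0 did not pass (26 adjusted over the list alone, camera adjusted p = 1.02e-10). Of 22 immediate early genes, 16 rose, 4 fell and 2 did not pass (20 adjusted over the list alone, median log2 fold change 0.60, camera adjusted p = 4.63e-04, adjusted p = 0.0872 with an estimated correlation). Transporters did not pass as a list, with a median of -0.41 and a mean of 0.04, opposite in sign (camera adjusted p = 0.318). Of the 13 mitochondrial genes, 0 rose, 12 fell and 1 did not pass (12 adjusted over the list alone, median log2 fold change -1.21, camera adjusted p = 6.18e-05, adjusted p = 0.126 with an estimated correlation). The count was 7916 changed genes, 3962 higher and 3954 lower, with a higher share of 54.5% when scaled without mitochondrial genes and the top 50 genes, 43.4% after quantile normalization and 46.2% among genes with a mean of at least 5 FPKM. The chromosome medians followed those of wild-type co-culture (chromosome 11 at -0.309 and chromosome 17 at 0.253). The call of mt-Cytb (-1.08) was lost under quantile normalization (-0.07, adjusted p = 0.487).

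Whether the inhibitor effect differs with the genotype of the cancer cells was tested as an interaction. The rise or fall of most genes did not differ past the threshold, but the immediate early genes that did differ had higher values of the interaction, that is a smaller fall or a larger rise with the inhibitor beside knockout cells, or a rise only there. Egr1 fell with the inhibitor beside wild-type cells, from 72.0 to 44.6 FPKM, and rose from 38.3 to 55.0 beside knockout cells (interaction log2 fold change 1.19 ± 0.05, adjusted p = 4.92e-09). Atf3, a stress-induced transcription factor, went from 33.3 ± 1.86 to 9.87 ± 1.08 FPKM beside wild-type and from 32.8 ± 1.12 to 23.9 ± 0.291 beside knockout cells (1.22 ± 0.08). Jun (0.93 ± 0.07), Fosb (1.22 ± 0.12) and Btg2 (0.85 ± 0.08) also differed. Fosb was already near 0 with the inhibitor in both genotypes (0.0862 and 0.108 FPKM), so its interaction rests on the difference without the inhibitor.

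Among the 22 immediate early genes, 8 were higher, 0 were lower and 14 did not pass, with 15 adjusted over the list alone (median log2 fold change 0.35, camera adjusted p = 1.18e-25, adjusted p = 0.00128 with an estimated correlation). Of 26 proliferation genes, 0 were higher, 4 were lower and 22 did not pass, with 12 adjusted over the list alone (median log2 fold change -0.21, camera adjusted p = 2.75e-12). Of 34 interferon-stimulated genes, 0 were higher, 2 were lower and 32 did not pass, with 7 adjusted over the list alone (median log2 fold change -0.16, camera adjusted p = 3.93e-07), and outside that list Ifi207, an interferon-inducible gene with close relatives and so uncertain, was at -0.94 ± 0.15. Single genes with calls in each alternative apart from the threshold on fold size included Ttr (-0.64 ± 0.08), Ccl2 (-0.66 ± 0.06), Hnf4a (0.37 ± 0.06), Nfkbiz (0.41 ± 0.06) and Cyr61 (0.45 ± 0.07). None of the genes Phgdh, Psat1, Psph, Shmt1, Shmt2 and Alb passed (adjusted p = 0.895, 0.563, 0.955, 0.212, 0.755 and 0.152). The unfolded protein response (median log2 fold change 0.13, camera adjusted p = 7.71e-09), cytochrome P450 (median log2 fold change 0.19, camera adjusted p = 1.29e-04) and p53 (median log2 fold change 0.20, camera adjusted p = 1.64e-04) lists were higher in the interaction, with 6 adjusted over the list alone, 4 adjusted over the list alone and 4 adjusted over the list alone. Also higher were transporters (1 was higher, 0 were lower and 16 did not pass, 1 adjusted over the list alone, median log2 fold change 0.13, camera adjusted p = 0.00383) and one-carbon metabolism (2 were higher, 0 were lower and 22 did not pass, 4 adjusted over the list alone, median log2 fold change 0.10, camera adjusted p = 0.0160). The same held for hepatocyte proteins and factors (1 was higher, 1 was lower and 17 did not pass, 7 adjusted over the list alone, median log2 fold change 0.13, camera adjusted p = 3.53e-04) and gluconeogenesis (1 was higher, 0 were lower and 8 did not pass, 1 adjusted over the list alone, median log2 fold change 0.09, camera adjusted p = 0.00217). The camera calls of ATF4 targets (0.00180, adjusted p = 0.0622 with an estimated correlation), NF-kB targets (0.00240, adjusted p = 0.0686 with an estimated correlation), fatty acid oxidation (0.00383, adjusted p = 0.0633 with an estimated correlation) and cholesterol (0.0130, adjusted p = 0.166 with an estimated correlation) were lost with an estimated correlation.

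The interaction was called in 93 genes, 61 higher and 32 lower beside knockout cells, out of 1239 at an unadjusted p under 0.05. Scaling without mitochondrial genes and the top 50 genes moved the higher share from 65.6% to 77.3%, with 66 genes. Leaving out 1 library gave 42 (monoculture 3), 52 and 43 (wild type 2 and 3), 31, 60 and 40 (knockout 1, 2 and 3), 33, 41 and 38 (wild type with inhibitor 1, 2 and 3), or 40, 36, 38 and 47 (knockout with inhibitor 1, 2, 3 and 4). Of 39 named calls 12 passed in each alternative apart from the threshold on fold size.

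Wild-type co-culture with the inhibitor against monoculture asks what differs from hepatocytes alone when the inhibitor is present. Ifit1 (0.408 to 60.8 FPKM, log2 fold change 5.46 ± 0.10), Ifitm3 (4.76 ± 0.20), Apol9b (5.17), Trim30a (5.02) and the vasodilator peptide gene Adm (4.68) were highest. The largest falls were Fos (93.4 to 1.76 FPKM, -5.09 ± 0.09), the cytokine Il11 (-4.50 ± 0.14), Bex1 (-4.36), Nrep (-4.33) and Evl (-3.63). Ccl2 stayed under its monoculture level (-1.59) while albumin exceeded it (57.1 to 335 FPKM, 2.53 ± 0.06). Phgdh (-0.38 ± 0.04), Psat1 (-0.99 ± 0.05) and Shmt1 (-0.63 ± 0.06) were lower and Shmt2 did not pass (adjusted p = 0.959). Psph passed (0.18 ± 0.06, adjusted p = 0.0226) but not without monoculture replicate 3 or wild-type inhibitor replicate 1 (adjusted p = 0.130 and 0.0859) or in the fit of only these groups (0.0807). The call of Ecm1 (0.24) was lost without monoculture replicate 1 or wild-type inhibitor replicate 3 (adjusted p = 0.0748 and 0.0769).

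Interferon-stimulated genes (33 rose, 1 fell and 0 did not pass of 34, 34 adjusted over the list alone, median log2 fold change 2.02, camera adjusted p = 2.81e-19) and hepatocyte proteins and factors (16 rose, 0 fell and 3 did not pass of 19, 17 adjusted over the list alone, median log2 fold change 1.14, camera adjusted p = 7.51e-08) stood above monoculture, as did glycolysis and hypoxia genes (23 rose, 1 fell and 2 did not pass of 26, 24 adjusted over the list alone, camera adjusted p = 4.35e-10). All 26 proliferation genes stayed below it (26 adjusted over the list alone, median log2 fold change -0.9996, camera adjusted p = 9.39e-11), and so did NF-kB targets (3 rose, 17 fell and 5 did not pass of 25, 21 adjusted over the list alone, camera adjusted p = 5.29e-05). The unfolded protein response list stayed above (18 rose, 1 fell and 0 did not pass of 19, 19 adjusted over the list alone, camera adjusted p = 1.09e-08). Calls lost with an estimated correlation were transporters (0.0452, adjusted p = 0.0789 with an estimated correlation), cholesterol (0.00120, adjusted p = 0.0789 with an estimated correlation), immediate early genes (0.00533, adjusted p = 0.174 with an estimated correlation) and mitochondrial transcripts (2.25e-04, adjusted p = 0.174 with an estimated correlation), of which all 13 genes fell. Chromosome 11 stood at -0.296 and chromosome 17 at 0.277. In total 7610 genes changed, 3657 higher and 3953 lower (48.1% higher), or 58.2% higher of 7468 when scaled without mitochondrial genes and the top 50 genes. With wild-type co-culture without the inhibitor, 4004 of them were shared in direction and 1239 opposite, where independent calls would give 2363. This overlap was added after seeing the data. Its r of 0.441 stood beside 0.512 simulated and its covariance of 0.191 beside 0.00803, so little of it comes from the shared monoculture.

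Knockout against wild-type co-culture, both with the inhibitor, asks about the genotype of the cancer cells in its presence. Atf3 was 9.87 ± 1.08 FPKM beside wild-type and 23.9 ± 0.291 beside knockout cells (log2 fold change 1.199 ± 0.06, adjusted p = 6.49e-08). Albumin was 335 ± 10.3 and 461 ± 9.61 FPKM (0.46 ± 0.05, adjusted p = 3.82e-04). The growth factor receptor gene Fgfr3 (0.63 ± 0.06) was higher, and Add2 (-0.50 ± 0.03), Acsbg1 (-0.56 ± 0.06) and Ifi207 (-0.68 ± 0.10) were lower beside knockout cells. The calls of Cyp2d26 (0.74), the nuclear receptor Nr0b2 (0.67) and Ifit3 (-0.53) were lost with a pseudocount of 0.1 (adjusted p = 0.116, 0.571 and 0.272), that of Nr0b2 also without wild-type inhibitor replicate 1 (0.0515). The call of Cldn6 (-0.53) was lost without any 1 of the 7 libraries compared (adjusted p up to 0.119).

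Of 19 hepatocyte proteins and factors, 9 were higher, 0 were lower and 10 did not pass, with 13 adjusted over the list alone (median log2 fold change 0.28, camera adjusted p = 2.45e-16). They included fibrinogen Fgb (0.49), Ttr (0.40) and the bile acid receptor Nr1h4 (0.28). Of 21 acute phase genes, 9 were higher, 0 were lower and 12 did not pass, with 10 adjusted over the list alone (median log2 fold change 0.23, camera adjusted p = 1.47e-12). Here C3 stood at 0.32 and Lbp at 0.23. Of 22 immediate early genes, 7 were higher, 0 were lower and 15 did not pass, with 8 adjusted over the list alone (median log2 fold change 0.16, camera adjusted p = 1.17e-12). Here Jun stood at 0.59 and Egr1 at 0.29. Of 12 cytochrome P450 genes, 6 were higher, 0 were lower and 6 did not pass, with 8 adjusted over the list alone (median log2 fold change 0.25, camera adjusted p = 9.16e-15). Here Gsta3 stood at 0.28. The serine genes did not pass (adjusted p = 0.655 for Phgdh, 0.923 for Psat1, 0.968 for Psph, 0.408 for Shmt1 and 0.670 for Shmt2). Fatty acid oxidation (median log2 fold change 0.15, camera adjusted p = 7.30e-12, 12 adjusted over the list alone) and gluconeogenesis (median log2 fold change 0.14, camera adjusted p = 7.06e-07, 4 adjusted over the list alone) were higher, and interferon-stimulated genes (median log2 fold change -0.09, camera adjusted p = 1.71e-04, 3 adjusted over the list alone) and glycolysis (median log2 fold change -0.11, camera adjusted p = 1.76e-06, 9 adjusted over the list alone) lower. Of 26 proliferation genes, 0 were higher, 2 were lower and 24 did not pass, with 4 adjusted over the list alone (median log2 fold change -0.11, camera adjusted p = 3.73e-08), opposite in sign to the genotype comparison without the inhibitor (median 0.09, camera adjusted p = 1.69e-04). NF-kB targets (5 were higher, 0 were lower and 20 did not pass, 9 adjusted over the list alone, median log2 fold change 0.09, camera adjusted p = 2.13e-08) were higher and the YAP list lower (1 was higher, 3 were lower and 19 did not pass, 4 adjusted over the list alone, median log2 fold change -0.08, camera adjusted p = 0.00111). Other lists that passed with a median above 0 were STAT3 targets (0.08, 2 adjusted over the list alone, camera adjusted p = 0.00266), lipogenesis (0.05, 3 adjusted over the list alone, 0.00587) and NRF2 targets (0.07, 2 adjusted over the list alone, 0.00650). The same held for the unfolded protein response (0.05, 2 adjusted over the list alone, 1.71e-04) and cholangiocyte genes (0.09, 3 adjusted over the list alone, 0.00155). Calls lost with an estimated correlation were one-carbon metabolism (0.0468, adjusted p = 0.0673 with an estimated correlation), transporters (0.0356, adjusted p = 0.0526 with an estimated correlation), ATF4 targets (0.00390, adjusted p = 0.0644 with an estimated correlation) and mitochondrial transcripts (0.0449, adjusted p = 0.421 with an estimated correlation).

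The genotype comparison with the inhibitor called 263 genes, 189 higher and 74 lower. Leaving out 1 library gave 123, 142 and 125 without wild-type inhibitor replicates 1, 2 and 3, and 156, 166 and 172 without knockout inhibitor replicates 1, 2 and 3, and array weights gave 523. With the genotype comparison without the inhibitor, which shares no library with it, 66 genes were shared in direction and 7 were opposite, against 4.11 for independent calls. This overlap was added after seeing the data. Of 57 named calls 26 passed in each alternative apart from the threshold on fold size.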

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

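The overlap between both genotype comparisons was chosen only after its result was seen. The tests on wild-type co-culture replicate 1 and on the direction of genes across both genotype comparisons, and the splits of the libraries, were chosen before.

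Within the knockout co-culture with the inhibitor (n = 4), 1 library lay far from the other 3 for Add2, at 9.66 FPKM in replicate 3 against 9.33 to 9.36 in the others, a gap of 0.901 of the group's range. A gap of 0.841 was marked for 1 more gene, which is not reported here. Values over 0.829 were marked, 53 genes were tested in this way, and chance marks about 1 in 20. The difference is small in FPKM.

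The inhibitor effect differed between genotypes in 93 genes by the interaction test. Among named genes, the highest interaction log2 fold changes were Atf3 (1.22), Fosb (1.22), Egr1 (1.19), Il11 (0.96) and Jun (0.93). The lowest were Ifi207 (-0.94), Mmp13 (-0.82), Lmcd1 (-0.70), Adcy9 (-0.68) and Ccnb1 (-0.68). Leaving out single libraries ended the calls of Il11 (13 of 16 libraries, adjusted p up to 0.117), Mmp13 (14, up to 0.119), Lmcd1 (11, up to 0.108), Adcy9 (14, up to 0.118) and Ccnb1 (13, up to 0.122). Of 100 splits of the libraries within the co-cultures without and with the inhibitor, 3 gave as many genes, the real one included. These splits exchange genotypes within each arm, so a genotype difference in either arm enters them as well. Their share therefore cannot decide whether chance gave the interaction count. The highest other split gave 189 genes, when knockout libraries 1, 2 and 4 with the inhibitor stood in for the 3 wild-type libraries with it. That split nearly exchanges both genotypes under the inhibitor, so it adds the genotype differences of both arms in place of setting them against each other. The next gave 107, with wild-type library 1 and knockout libraries 1 and 3 as a group without the inhibitor and knockout libraries 1, 2 and 3 in place of the wild-type ones with it, so genotypes are again nearly exchanged under the inhibitor. The same group without the inhibitor gave 77 genes with the real groups under the inhibitor.

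The pattern that hepatocytes differed with the Phgdh genotype of the cancer cells was weighed. Without wild-type co-culture replicate 1, the library that stood apart, 398 genes changed against 341, but only 260 genes were called in both. Counts also rose without it where it was not compared (263 to 371 for genotype with the inhibitor), and all groups share 1 estimate of the spread per gene. The rise therefore cannot show whether the count rested on that library. An effect of the genotype that is also present with the inhibitor stays open, since 69.8% of the genes called without the inhibitor had the same sign with it, between the bounds set for and against it, and 66 genes were called in both with the same direction, while the medians of the proliferation list (0.09 without and -0.11 with the inhibitor) and the immediate early genes (-0.17 and 0.16) were opposite in sign. The 10 splits without the inhibitor are too few for a share under 0.05, with 341 genes in the real split and 142 in the highest other, that of wild-type library 1 with knockout libraries 1 and 3. With the inhibitor, 1 of 35 splits gave as many genes, the real one (263, highest other 1), so chance is excluded at 0.05 there. A difference between culture batches that follows the genotype may also give such counts and was not tested, because the labels name no batch.

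For the inhibitor in knockout co-culture, 1 of 35 splits gave as many genes, the real one (7916), a share under 0.05 with the same limits. The highest other gave 5424, in which 1 library with the inhibitor joined the 3 without it, as in 3 more splits (5233 to 5421 genes).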

How the results depend on the processing

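Removal of chromosome medians, removal of GC and length bins, and the fit without the inhibitor libraries were chosen only after the results were seen. Over all alternatives 390 counts stayed within 1.5 times the reported value and 43 did not. Of the calls and values of named genes, 23432 kept direction and side of the threshold, 1283 lost the call, 23 gained one, 72 without a call changed sign, and no call reversed. For lists these numbers were 4879, 87, 36 and 47. With an absolute log2 fold change of at least 1, fewer genes can pass by construction. Counts were then 1020 and 978 for wild-type and knockout co-culture against monoculture, 2 for genotype, 1194 and 1242 for the inhibitor in wild-type and knockout co-culture, 4 for the interaction, 1096 for wild-type co-culture with the inhibitor against monoculture and 2 for genotype with the inhibitor. Overlaps were then 878 for both co-cultures, 430 for genes opposite with the inhibitor and 2 for genotype with inhibitor. A fit of only the libraries compared gave 17 genes for genotype and 41 for the interaction, and array weights gave 1384, 623 for the interaction and 523 for genotype with the inhibitor. No filter gave 55 and a replicate block 34 for the interaction, and the fit without the 7 inhibitor libraries 82 for genotype (81 of them shared with the 341). Leaving out 1 library gave 157 to 398 for genotype, 31 to 120 for the interaction and 123 to 371 for genotype with the inhibitor. With an estimated correlation 7 lists passed for genotype in place of 13. Fewer libraries alone do not explain the 17 genes, since such a fit gave 254 for genotype with the inhibitor (263 reported). The causes were not tested. Both co-cultures against monoculture, both inhibitor effects and the inhibitor co-culture against monoculture stayed within 1.5 times in all other alternatives. All alternatives chosen before the results were seen were run. Depth limits low genes, since 1 fragment in a 1 kb gene is 0.0457 to 0.0648 FPKM, and calls of genes near 1 FPKM, such as Nr0b2, depended on the pseudocount (adjusted p = 0.571 at 0.1).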

Other observations

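The tests on a shift of all genes alike, on the size of the rescaling, on dilution by cancer cell RNA and on cancer cell markers were chosen only after the results were seen, and the removal of GC and length bins after the chromosome pattern was seen.

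Further metabolic lists moved with co-culture or with the inhibitor, not all of them past the threshold. Of 9 gluconeogenesis genes, 5 rose, 1 fell and 3 did not pass in wild-type co-culture (6 adjusted over the list alone, median log2 fold change 0.37, camera adjusted p = 0.0219, adjusted p = 0.102 with an estimated correlation). Rises included the mitochondrial carboxykinase Pck2 (1.47) and the aspartate transaminase Got1 (1.25). Of 25 fatty acid oxidation genes, 4 rose, 15 fell and 6 did not pass (19 adjusted over the list alone, median log2 fold change -0.19, camera adjusted p = 0.0261, adjusted p = 0.119 with an estimated correlation). Here Cpt1a stood at -0.82 and the thioesterase Acot2 at 2.40. With the inhibitor 18 rose, 3 fell and 4 did not pass (22 adjusted over the list alone, median log2 fold change 0.34, camera adjusted p = 2.61e-04). The pyruvate dehydrogenase kinase Pdk4 rose (2.83). Of 9 urea cycle and nitrogen genes, 6 rose, 1 fell and 2 did not pass with the inhibitor (7 adjusted over the list alone, median log2 fold change 0.97, camera adjusted p = 0.00655). The carbamoyl phosphate synthetase Cps1 went from 0.0975 ± 0.0274 to 10.7 ± 0.525 FPKM (3.41) and Ass1 from 3.103 ± 0.233 to 31.2 ± 2.32 (2.97). In co-culture without it this list did not pass (2 rose, 4 fell and 3 did not pass, camera adjusted p = 0.247), with the glutamate dehydrogenase Glud1 at -1.25.

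Of 13 NRF2 targets, 8 rose, 1 fell and 4 did not pass with the inhibitor (9 adjusted over the list alone, median log2 fold change 0.31, camera adjusted p = 0.0162). The glutathione synthesis gene Gclc stood at 1.24 and Gsta4 at 1.35 (uncertain, as close relatives exist), while in co-culture alone the list did not pass (camera adjusted p = 0.278). The p53 list did not pass in either comparison (in co-culture 3 rose, 4 fell and 8 did not pass, 6 adjusted over the list alone, camera adjusted p = 0.952, and with the inhibitor 6 rose, 7 fell and 2 did not pass, 13 adjusted over the list alone, camera adjusted p = 0.870), Trp53inp1 rising (1.17) and Plk2 falling (-1.21) in co-culture. Of 6 cholangiocyte genes, 0 rose, 5 fell and 1 did not pass in co-culture (5 adjusted over the list alone, median log2 fold change -1.56, camera adjusted p = 1.89e-04). Members were osteopontin Spp1 (1016 to 315 FPKM, -1.69) and Bicc1 (-1.44). With the inhibitor, 5 rose, 1 fell and 0 did not pass (camera adjusted p = 0.0173). Of 18 stellate cell genes 1 was tested, Ecm1, which fell in wild-type (-0.51) and knockout co-culture (-0.79) and rose with the inhibitor in both (0.75 and 0.97). It stood at 0.24 in wild-type co-culture with the inhibitor against monoculture (not past the threshold without monoculture replicate 1 or inhibitor replicate 3, adjusted p = 0.0748 and 0.0769), and of the untested stellate cell genes Postn was highest (0.377 FPKM). Of 18 Kupffer cell genes 1 was tested, Cd68, and of the others Mrc1 was highest at 0.401 FPKM. None of 17 endothelial and 12 neutrophil genes was tested, the highest being Ptprb (1.64 FPKM) and S100a8 (0.271 FPKM).

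The libraries with the inhibitor stood apart from all other libraries. A small RNA or mitochondrial RNA content that differs between library preparations was tested by rescaling. Without the top 50 and mitochondrial genes, all genes moved by a median of 0.0293. Called genes had a median change of 0.466 in absolute size, and 7418 genes changed after rescaling (7584 before). For a shift of all genes alike from such a share, 329 genes fell and 865 rose at least 2-fold. The median log2 fold change of all genes was already near 0 in the deposited values (-0.00716), so neither test can decide. GC content or gene length bias was argued against as the cause of the chromosome pattern, as the chromosome 11 median stayed at -0.301 after removal of those bins. A different cell stock or subclone with a different chromosome complement may explain the part of the pattern that follows chromosomes, since the largest chromosome median reached 0.334 in absolute size for the inhibitor against 0.0827 in co-culture. It met the prediction and stays open beside an effect of the inhibitor itself, because every library with the inhibitor shows it and none without, so both cannot be told apart here.

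Cell cycle genes fell and stress response genes rose in co-culture. Dilution of the hepatocyte RNA by RNA from the cancer cells was argued against only as the cause of falls as deep as those of the proliferation list. The 19 members of the hepatocyte identity list had a median log2 fold change of -0.50 (SD 0.839) against -2.61 for proliferation. Smaller falls are not covered by that test, since 13 of the 19 identity members fell themselves and a smaller share of other RNA could contribute to them. RNA from the cancer cells could still contribute to the genes that rose. Of 13 members of the pancreatic cancer epithelium list under 1 FPKM in monoculture 0 reached 1 FPKM in co-culture (highest Ctse, 0.667), which does not exclude a small share, because the profile of these cancer cells was not measured. A response to the cancer cells is a candidate explanation that the design gives and that these tests leave open.

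For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. In wild-type co-culture against monoculture the real split gave 7070 genes and the highest other 2, in knockout co-culture 7011 and 0, for the inhibitor in wild-type co-culture 7584 and 1, and for wild-type co-culture with the inhibitor against monoculture 7610 and 1. In each of these comparisons 1 split, the real one, gave as many genes.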
